A study of Mus musculus with 28 samples.

How the data were processed

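The series measured liver messenger RNA by sequencing in 28 samples from male mice of the C57BL/6 strain, given in 3 tables of 20416 genes each. The table of the methionine- and choline-deficient diet (MCD) held 4 MCD livers and 4 livers of the matched control diet (CD). The tables of the STAM model, in which newborn mice receive streptozotocin, a toxin of pancreatic beta cells, and later a high-fat diet, held 5 STAM and 5 control livers at 4 weeks and again at 10 weeks of age. Groups and replicate numbers were taken from the sample titles. For the diet table the titles give 4 weeks, whereas another label gives a study duration of 5 weeks, and the groups are called MCD and CD throughout. The labels name the replicates as separate samples without saying that each came from its own mouse, so p-values measure only the spread between these samples, which may be technical.

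Per the labels' protocols, RNA was column-purified after lysis in Trizol, libraries were made with a stranded poly(A) kit, and both ends of fragments were sequenced. Alignment with STAR 2.4.2a to the mm10 build is named in the submitters' processing notes. The read counter, the annotation release, any filter and the authors' statistical test are not given in the sources used here. Each deposited sample column held log2 CPM (counts relative to an effective library size), which the authors scaled within each table, with a small prior count. This reading of the unit came from the values. Every sample of a table had the same minimum, and after subtraction of a prior of 0.25 reads 100% of the deposited values of each sample were whole reads within a tolerance of 0.05 reads. Log2 fold changes and average log2 values per gene were also in the deposited tables, per the file headers. The p-values and adjusted p-values of the authors stood beside them, and the adjusted ones equalled Benjamini-Hochberg values to within 2.83e-15. A gene length in bases was not used. All 28 per-sample columns were used.

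Effective library sizes recovered from the values were divided by the total recovered reads to give a scaling factor per library, which lay between 0.832 and 1.23. Since scaling was done by the authors separately per table, tests of groups were run within a table and difference tests compared effects within tables. Levels were set side by side across tables only to place 1 library between the control livers of both ages. Recovered totals were 16.2 to 25.9 M reads per library. At these depths 3 reads over 1 library correspond to at most 0.200 CPM, and genes with no read in any library of a table numbered 4055, 3948 and 4044 for the MCD, 4-week and 10-week tables. Where all libraries of a group had no read, a fold change is given as a bound against a floor of 3 reads over the group. With 1 to 3 reads in a group the ratio of reads is given with its exact counting interval. Reads were not marked with molecular identifiers in the sources used here, so intervals and floors cover counting error only. No pair of replicates agreed within sampling noise, as the lowest chi-square per degree of freedom of a replicate pair was 11.4.

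Gene positions are those of the deposited tables on mm10, with 1 added to each start, because 10880 of 19397 genes on the same chromosome matched RefSeq GRCm38.p6 starts after this step and 688 matched as deposited. Of the 20416 symbols, 19405 were in that RefSeq table. Reads of near-identical genes, such as the Mup, Cyp2, Cyp3a, Cyp4a, Sult and Ugt families, may have been split among members by a rule not given in the sources used here, and values of such genes are uncertain.

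The tests, the sample groups, the gene lists and the alternatives were fixed before the data were examined, except where stated. A count model had been planned for raw counts; because the deposited unit is log2, the test planned for that unit was used instead. Each comparison was fitted alone with limma 3.58.1 (R 4.3.3, with statmod 1.5.0), with a mean-variance trend and robust variance estimation, on genes above the 25th percentile of mean value in the table. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Difference tests used 1 fit over 4 groups and the genes tested in both tables. The age test was the STAM effect at 10 weeks minus the STAM effect at 4 weeks, and the model test was the MCD effect minus the STAM effect at 10 weeks. Confidence intervals are 95% intervals of limma. Fold-change correlations were computed across genes with Spearman's rho for 3 pairs of comparisons that share no control library, with a jackknife standard error over libraries and no p, since genes are not independent replicates.

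In all, 34 gene lists with 622 genes were tested, of which 616 had a line in the tables and 2 were in more than 1 list. Pathway lists covered collagen and matrix remodelling, proliferation, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation and PPAR alpha targets, lipid droplets, gluconeogenesis, glycolysis, bile acids, male-biased and female-biased liver genes, NRF2 targets, methionine and choline metabolism, the integrated stress response, the unfolded protein response, the acute phase, inflammatory cytokines, the interferon response, the circadian clock, fetal and tumour genes, and pericentral and periportal hepatocyte genes. Marker lists covered stellate cells, recruited macrophages, Kupffer cells, T and NK cells, B cells, neutrophils, sinusoidal endothelium, cholangiocytes, erythroid cells, exocrine pancreas, adipocytes and core hepatocyte genes. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists with Benjamini-Hochberg. Beside it stand camera with an estimated correlation and the number of called members over all genes and adjusted over the list alone. For the rotation test fry, the number of lists called is given, with adjusted p of some lists that only camera called. Camera on the difference tests was added after the data were seen. Members count as risen or fallen when called over all genes tested.

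Genes are named by a rule fixed in advance. It takes the 5 largest rises and 5 largest falls per comparison among called genes above the median expression with no overlap between groups, for the difference tests without the overlap condition. It adds the 3 called members with the largest change in each list that camera called, and 24 genes for every comparison whether called or not. Of the 24, 22 are given, and some genes that the rule takes are not reported here. Other members are named where they were exceptions in a list or where 5 or fewer members were called. Any further gene was chosen after its values were seen, which is said beside it.

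Alternatives were limma without trend and robust estimation, quantile normalization, no filter, a filter at the median of all genes, a minimum log2 fold change of 1, the replicate number as a block, fry, the estimated correlation, Pearson's correlation, correlations over called genes, and leaving out each library in turn. Voom on the recovered reads, scaling by total reads, a prior of 2 reads and leaving out the replicate 1 controls of both ages were added after the data were seen. Other splits of the samples into groups of the same sizes were counted, all 35 for the MCD table and 100 drawn with a fixed seed for the others, the real split included.

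The procedure was tested on simulated reads with known changes. Every gene of a table was drawn with the same relative spread, taken from its controls, few genes were changed, and libraries were scaled by total reads. No simulated library stood apart from its group. The shares below may therefore not carry over to the real data. For the MCD comparison it recovered 71.6% of 67 genes changed 1.5-fold and 97.0% of 67 genes changed 2-fold, with 6 false calls among 183 over 15297 genes. At 4 weeks of STAM the same shares were 86.6% and 97.0%, with 6 false calls among 195 over 15310 genes, and at 10 weeks 83.6% and 97.0%, with 8 false calls among 194 over 15312 genes. For the age test, 92.5% of 200 genes whose effect differed 2-fold were recovered, with 7 false calls among 192 over 14826 genes.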

Results

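Liver RNA was compared between diseased and control male mice in 2 models of non-alcoholic steatohepatitis, a liver disease with fat storage, inflammation and scarring. The diet model had 4 livers on a methionine- and choline-deficient (MCD) diet and 4 on the matched control diet (CD). The STAM model, which joins loss of insulin-producing cells with a high-fat diet, had 5 STAM and 5 control livers at each of 2 ages, 4 and 10 weeks. Recovered reads per library were 18.0 to 22.8 M in CD, 20.3 to 25.9 M in MCD, 16.2 to 20.8 M in 4-week controls, 18.6 to 22.1 M in 4-week STAM, 17.2 to 24.2 M in 10-week controls and 18.0 to 25.3 M in 10-week STAM livers. More genes had reads in diseased livers, with 15129 to 15327 in MCD against 14273 to 14625 in CD, and 14917 to 15142 in 10-week STAM against 14291 to 14506 in controls. Alb, which encodes serum albumin, took 5.40% ± 0.909 of reads in CD (SD, n = 4) and 7.72% ± 0.782 in MCD (SD, n = 4). Its share was 11.02% ± 0.646 and 9.22% ± 0.565 in 4-week control and STAM livers, and 6.44% ± 0.976 and 4.07% ± 0.753 in 10-week control and STAM livers (SD, n = 5 each).

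The first comparison asked which liver transcripts differed on the MCD diet, which withholds the precursors of phosphatidylcholine. In MCD livers, genes of fatty acid synthesis, male-biased hepatocyte genes and genes of protein folding in the endoplasmic reticulum fell. Genes of recruited macrophages, scar matrix, lipid droplets, cell division and the amino acid stress response rose. Of 15312 genes tested with limma, 6541 were called, 3462 higher and 3079 lower, and 2637 of them changed by at least 1 on the log2 scale. When libraries were scaled by total reads, the median log2 fold change moved up by 0.42, and 86.1% of 8810 called genes were higher, against 52.9% as reported and 49.2% with quantile normalization. Directions are therefore relative to the authors' scaling.

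Scd1 (NM_009127, chromosome 19, 44394450 to 44407709), the enzyme that makes monounsaturated fatty acids, dropped from 13.75 ± 0.51 to 6.37 ± 1.14 log2 CPM (mean ± SD, n = 4 per group), 166-fold lower. On the log2 scale it fell by 7.38 (95% interval -8.73 to -6.02, limma adjusted p = 5.78e-05). Elovl3 (NM_007703, chromosome 19, 46131899 to 46135694), which lengthens fatty acids, fell by 6.49 (SE 0.44, limma adjusted p = 2.3e-05). In the list of fatty acid and triglyceride synthesis, 15 of 20 genes fell, also when adjusted over the list alone. Among them were Pnpla3, a lipase of lipid droplets, which fell by 4.72, and the acetyl-CoA synthetase Acss2, which fell by 2.11. Camera called the list (adjusted p = 1.72e-07, and adjusted p = 0.306 with an estimated correlation). With total-read scaling 9 members fell and 1 rose, and with quantile normalization 10 fell and 2 rose. Fasn, the fatty acid synthase, fell by 1.74 (limma adjusted p = 0.0267) and its regulator Srebf1 fell by 1.41 (limma adjusted p = 0.0174). The Fasn call was lost without MCD replicate 1, 2 or 4 (limma adjusted p = 0.0675, 0.0573 and 0.0747), under quantile normalization (0.110) and with total-read scaling (0.0597), where Srebf1 was also lost (0.0551). Genes of lipid droplets moved the other way, with 10 of 16 higher. Cidec, a droplet coat protein, rose by 5.67 (50.8-fold), the adipogenic receptor Pparg by 3.30 and the fatty acid importer Cd36 by 3.18 (SE 0.09, limma adjusted p = 6.1e-10). The count adjusted over the list alone was also 10 (camera adjusted p = 0.000217, and adjusted p = 0.191 with an estimated correlation).

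Among other metabolic lists, 12 of 21 bile acid genes fell, 13 when adjusted over the list alone, led by Cyp7b1 (by 3.72), the bile acid importer Slc10a1 (by 2.73) and Slc27a5 (by 2.35). Camera called it lower (adjusted p = 0.00272, and adjusted p = 0.355 with an estimated correlation), although 7 rose and 9 fell with total-read scaling. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.33 (SE 0.22, limma adjusted p = 1.77e-05), as did the exporters Abcc4 and Abcb4, whereas Cyp8b1, which sets cholic acid output, fell by 1.56 (SE 0.15, limma adjusted p = 5.12e-06). Of 13 gluconeogenic genes, 8 fell, 9 when adjusted over the list alone. They included Sds (by 1.01), Pcx (by 0.86) and Gls2 (by 0.77), while Igfbp1 rose by 2.54. The list's camera call (adjusted p = 0.0237, and adjusted p = 0.327 with an estimated correlation) was lost without MCD replicate 1 (0.0577), and 1 member fell and 1 rose with total-read scaling. Sds lost its limma call when any of 7 libraries was left out, for example CD replicate 1 (adjusted p = 0.0788), and Pcx under quantile normalization (0.161) and with total-read scaling (0.0502). Fgf21, a fasting hormone of the liver, rose by 4.24 (SE 0.24, limma adjusted p = 1.37e-07) and the fatty acid omega-hydroxylase Cyp4a14 by 5.30 (SE 0.82, limma adjusted p = 0.00198). Log2 fold changes were 0.29 for Cpt1a, the carnitine transferase of fatty acid oxidation, and 0.35 for Pck1 (limma adjusted p = 0.237 and 0.627). Cpt1a rose with total-read scaling (limma adjusted p = 0.00613) and quantile normalization (0.00299).

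Markers of recruited macrophages were higher in 16 of 19 cases, 17 when adjusted over the list alone, with only Fabp5 lower (by 3.54). Gpnmb, a membrane protein of lipid-laden macrophages, rose by 7.40 (169-fold, SE 0.60, limma adjusted p = 2.73e-05), the elastase Mmp12 by 7.21 (149-fold), Cd63 by 3.55 and Trem2 by 3.08 (limma adjusted p = 1.07e-05). Inflammatory cytokines rose in 16 of 20 cases, 17 when adjusted over the list alone, including Ccl3 by 3.20, Ccl7 by 3.12, Ccl2 by 2.98 and Tnf by 2.31 (limma adjusted p = 0.00013 for Tnf). Cxcl2 had 1 read in CD and 138 in MCD, a ratio of 95.2 (counting interval 16.8 to 3787). Camera called both lists (adjusted p = 1.24e-07 and 1.17e-07, and adjusted p = 0.306 with an estimated correlation for each). The Kupffer cell markers Clec4f and Timd4 had log2 fold changes of -0.04 and -0.02 (limma adjusted p = 0.884 and 0.957). Timd4 stood at 4.35 log2 CPM in MCD replicate 4 and at 2.81 to 2.91 in the other MCD livers, so its mean change depends on that library.

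Scar matrix genes rose in 25 of 32 cases, 28 when adjusted over the list alone, and in 31 with total-read scaling. Quantile normalization gave 25 higher and 1 lower. Mmp13, a collagenase, rose by 3.83 (SE 0.30), Timp1, an inhibitor of matrix proteases, by 2.86 (SE 0.49), the collagen cross-linker Lox by 2.81 and Col1a1, the main chain of type I collagen, by 1.57 (limma adjusted p = 0.000195). Stellate cell markers rose in 8 of 17 cases and Colec11 fell by 0.42, with Pdgfra up by 1.53 and Tagln by 1.47. Camera called both lists (adjusted p = 8.27e-09 and 0.0208, and adjusted p = 0.306 with an estimated correlation for each). Acta2, the actin of activated stellate cells, had a log2 fold change of 0.84 (limma adjusted p = 0.161) and was called without CD replicate 3 (0.0448) and with total-read scaling (0.0361). Ductular markers rose in 8 of 14 cases, 9 when adjusted over the list alone, with Cldn4 up by 4.85, Krt23 by 4.34 and Prom1 by 2.30 (camera adjusted p = 0.0019, and adjusted p = 0.306 with an estimated correlation). Proliferation genes rose in 22 of 27 cases, 23 when adjusted over the list alone, while Tk1 fell by 1.55 (camera adjusted p = 1.05e-06, and adjusted p = 0.385 with an estimated correlation). Ccnb1, a mitotic cyclin, rose by 3.12, Cenpf by 3.02, Cdc20 by 2.84 and Mki67, the Ki-67 marker, by 2.06 (limma adjusted p = 0.0119 for Mki67). Cenpf lost its call without CD replicate 4 (0.0606) or MCD replicate 4 (0.0563). Afp, the fetal form of albumin, rose by 2.26 (limma adjusted p = 9.66e-05).

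Genes that differ between male and female mouse liver also changed. Among called genes above the median expression with no overlap between groups, the highest rise was in Cyp2b9 (NM_010000, chromosome 7, 26173409 to 26210660), a cytochrome P450 of female liver. It went from 0.21 ± 1.14 to 8.46 ± 0.31 log2 CPM (mean ± SD, n = 4 per group), a 303-fold rise (limma adjusted p = 1.86e-05). Cyp2a4 (NM_009997, chromosome 7, 26307192 to 26315088) rose 102-fold and the oestrogen sulphotransferase Sult1e1 (NM_023135, chromosome 5, 87575968 to 87591611) 97.1-fold. Slc16a5 (NM_001080934, chromosome 11, 115462473 to 115474398), a monocarboxylate carrier, rose 57.6-fold and Cyp2a22 (NM_001101467, chromosome 7, 26931631 to 26939386) 43.6-fold (limma adjusted p of all 5 from 6.1e-10 to 0.000381). The major urinary protein gene Mup7 (NM_001134675, chromosome 4, 60066469 to 60070475) fell from 2550 to 2.18 CPM, that is by 10.17 on the log2 scale (SE 0.47). Mup14 (NM_001199999, chromosome 4, 61300037 to 61303998) fell by 8.14 and the organic anion carrier Slco1a1 (NM_013797, chromosome 6, 141907281 to 141946962) by 6.47 (limma adjusted p = 2.71e-06 and 0.000161). Male-biased genes fell in 15 of 16 cases, in 15 when adjusted over the list alone and in 15 with total-read scaling (camera adjusted p = 9.6e-13, and adjusted p = 0.191 with an estimated correlation). Female-biased genes rose in 14 of 18 cases, 15 when adjusted over the list alone, with Cyp2c69 lower by 2.44 (camera adjusted p = 1.24e-07, and adjusted p = 0.0563 with an estimated correlation). Cyp3a41a rose by 9.51 and Cyp3a44 by 9.17, and Cyp2b13 had 3 reads in CD and 1655 in MCD, a ratio of 381 (counting interval 130 to 1847). Moxd1, with 580 reads in CD and 1 in MCD (ratio 841, counting interval 150 to 33262), lost its limma call under voom (adjusted p = 0.179) and with a prior of 2 reads (0.0531). Most of these genes belong to families of near-identical members, so the split of reads among them is uncertain.

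Genes of the unfolded protein response, which serve folding in the endoplasmic reticulum, fell in 15 of 16 cases, 16 when adjusted over the list alone and 14 with total-read scaling. Sdf2l1 fell by 2.96, Creld2 by 2.41 and the chaperone Hyou1 by 1.41 (camera adjusted p = 7.63e-11, and adjusted p = 0.232 with an estimated correlation). In contrast 17 of 22 genes of the integrated stress response rose, 17 also when adjusted over the list alone. Aldh1l2 rose by 5.07, the kinase-like inhibitor Trib3 by 4.99 and Nupr1 by 4.82 (camera adjusted p = 2.43e-08, and adjusted p = 0.191 with an estimated correlation). Interferon response genes fell in 16 of 23 cases, 17 when adjusted over the list alone. Bst2 fell by 1.49, Mx2 by 1.40 and the transcription factor Irf7 by 1.28, while Rsad2 and Gbp2 rose by 0.55 and 0.49. With total-read scaling 7 fell and 2 rose (camera adjusted p = 3.98e-06, and adjusted p = 0.306 with an estimated correlation). Acute phase genes fell in 8 of 20 cases, 9 when adjusted over the list alone. Crp fell by 1.86, Fgg by 1.77 and Fga by 1.67, whereas Lcn2 rose by 3.07 and Apcs by 2.06. Camera's call (adjusted p = 0.0162, and adjusted p = 0.597 with an estimated correlation) was lost without MCD replicate 2 (0.0698), and 5 members rose against 7 lower with total-read scaling.

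Core hepatocyte genes fell in 12 of 18 cases, also when adjusted over the list alone, for example Hpd by 1.32, Tdo2 by 1.12 and Apoa1 by 1.11, while Cyp3a11 and Ahsg rose by 2.58 and 0.58. With total-read scaling 10 fell and 4 rose, and under quantile normalization 3 fell and 4 rose, with Apoa1 at 0.04 (camera adjusted p = 0.00224 as reported, and adjusted p = 0.385 with an estimated correlation). Alb itself had a log2 fold change of 0.10 (limma adjusted p = 0.644), which was 0.53 with total-read scaling (0.0061). Periportal genes fell in 10 of 13 cases, including Pigr (by 1.69), Cyp2f2 (by 1.54) and Etnppl (by 1.49), and Aldh1b1 rose by 1.10 (camera adjusted p = 0.000818, and adjusted p = 0.306 with an estimated correlation). Nqo1, a target of the oxidant sensor NRF2, rose by 1.33 (limma adjusted p = 0.000831). The 16 other lists were not called by camera. Among them, 10 methionine and choline genes fell and 6 rose of 30, and the list had a median of -0.15 with a mean of 0.23 (adjusted p = 0.328). NRF2 targets had 8 higher and 4 lower of 24, with a median of -0.06 and a mean of 0.81 (adjusted p = 0.478). Fatty acid oxidation had 10 higher and 11 lower of 31 (adjusted p = 0.703) and cholesterol synthesis 8 higher and 9 lower of 24 (0.537). Kupffer cell markers had 3 higher and 1 lower of 11 (0.744) and sinusoidal endothelial markers 4 lower of 14 (0.263), which became 6 higher with total-read scaling. In all, camera called 18 of 34 lists, 9 in each direction, and fry called 22, with these 18 among them. With an estimated correlation the lowest adjusted p of camera was 0.0563.

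**Figure D1:**
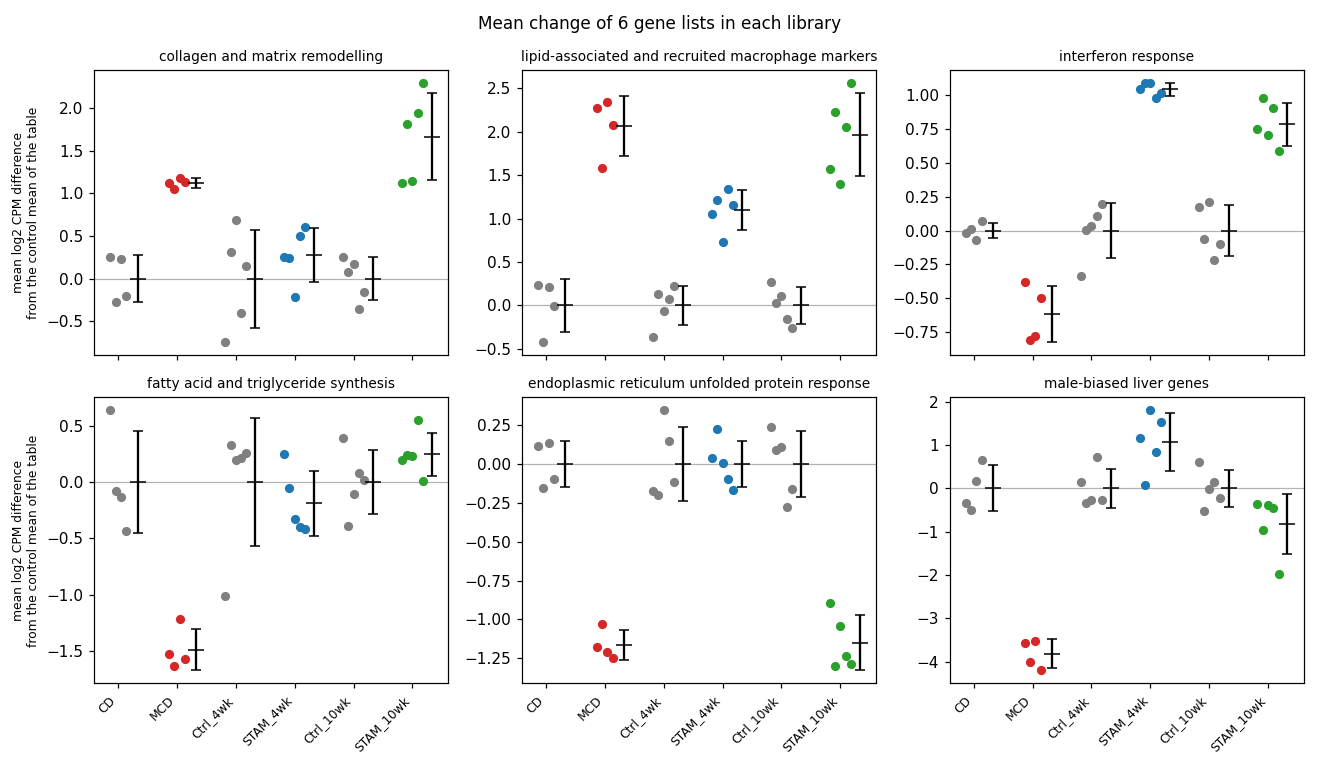
Mean log2 CPM of 6 gene lists in each library (points) as a difference from the mean of its own control group, with bars for the mean ± SD of each diseased group and its controls. The collagen score was 1.12 ± 0.05 in MCD, 0.28 ± 0.32 in STAM at 4 weeks and 1.67 ± 0.51 at 10 weeks, and the interferon score was -0.62 ± 0.21, 1.04 ± 0.05 and 0.78 ± 0.16 in the same order (n = 4, 5 and 5).

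The second comparison asked what differed in STAM livers at 4 weeks of age. By the design text the high-fat diet began in that week, while the labels of these livers name a high-fat diet, so how long they had received it is not given in the sources used here. The comparison thus does not separate streptozotocin from the diet. Interferon response genes, macrophage markers and 8 of 15 fetal and tumour genes rose in these livers, and collagen genes mostly did not pass the test. Limma called 1500 of 15312 genes, 999 higher and 501 lower, and 480 of them by at least 1 on the log2 scale. Without STAM replicate 1 the count was 982, and without 4-week control replicate 1, which stood apart from the other controls in 475 of 10208 genes by more than 2-fold, it was 1821. Total-read scaling moved the median by 0.08 and gave 83.7% higher among 1650 called genes, against 66.6% as reported.

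Interferon response genes rose in 20 of 23 cases, 22 when adjusted over the list alone and 21 with total-read scaling. Oas1a, which senses viral RNA, rose by 1.91 (SE 0.17), Ifi44 by 1.73 and Irf7 by 1.51 (2.84-fold, limma adjusted p = 8.57e-07). Camera called the list (adjusted p = 1.94e-27, and adjusted p = 0.132 with an estimated correlation). Macrophage markers rose in 15 of 19 cases, 15 also when adjusted over the list alone. Mmp12 rose by 4.77 (SE 0.42), Gpnmb by 4.28 (SE 0.39, limma adjusted p = 2.94e-05) and Trem2 by 1.97 (SE 0.37, limma adjusted p = 0.00527). Cytokines rose in 9 of 20 cases, 13 when adjusted over the list alone, including Ccl4 by 3.85, Cxcl9 by 1.66 and Ccl2 by 1.46 (limma adjusted p = 0.0109 for Ccl2). Camera called both lists (adjusted p = 1.67e-11 and 4.39e-07, and adjusted p = 0.132 with an estimated correlation for each). Cxcl2 rose by 3.02 (limma adjusted p = 0.0454), a call lost under quantile normalization (0.0807) and without any of 7 libraries, such as STAM replicate 4 (0.113), and Tnf had a log2 fold change of 0.89 (0.185). Kupffer cell markers rose in 6 of 11 cases, 8 when adjusted over the list alone, with C6 up by 2.13, the scavenger receptor Marco by 1.62, Cd5l by 0.76 and Clec4f by 0.44 (limma adjusted p = 0.0149 for Clec4f). C6 is also in the list of male-biased genes, so its rise counts in both lists. Camera called the list (adjusted p = 0.000687, and adjusted p = 0.405 with an estimated correlation). Timd4 had a log2 fold change of 0.35 (limma adjusted p = 0.154) and was called without STAM replicate 5 (0.0491). Of 19 T and NK cell markers 2 rose, Ccl5 by 1.06 and Il2rb by 0.83. This list's camera call (adjusted p = 0.0169, and adjusted p = 0.378 with an estimated correlation) was lost without STAM replicate 4 (0.0603) and with total-read scaling (0.0774). Ccl5 was lost without STAM replicate 1 (limma adjusted p = 0.0524) and under quantile normalization (0.0848).

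Fetal and tumour genes rose in 8 of 15 cases, 8 also when adjusted over the list alone. The growth factor Igf2 rose by 6.06 (66.7-fold, SE 0.32, limma adjusted p = 1.37e-06), Ly6d by 5.23 (37.6-fold) and Afp by 2.17 (limma adjusted p = 0.00892), and Dlk1 had 3 reads in controls and 43 in STAM, a ratio of 12.2 (counting interval 3.92 to 61.7). Camera called the list (adjusted p = 7.04e-06, and adjusted p = 0.168 with an estimated correlation). Lipid droplet genes rose in 6 of 16 cases, 9 when adjusted over the list alone, including Cidec by 3.08, Apoa4 by 2.25 and Cd36 by 1.60 (camera adjusted p = 7.41e-07, and adjusted p = 0.174 with an estimated correlation). Of 24 NRF2 targets 3 rose, 10 when adjusted over the list alone, namely the cystine importer Slc7a11 by 4.69, Cbr3 by 4.19 and Srxn1 by 1.0 (camera adjusted p = 5.85e-05, and adjusted p = 0.373 with an estimated correlation). Nqo1 had a log2 fold change of 0.41 (limma adjusted p = 0.41). Ductular markers rose in 5 of 14 cases, 7 when adjusted over the list alone, with Cldn4 up by 1.83, Cldn7 by 1.78 and Cftr by 1.63 (camera adjusted p = 0.00182, and adjusted p = 0.378 with an estimated correlation). Cldn7 lost its limma call without any of 7 libraries, such as STAM replicate 4 (adjusted p = 0.0891). Glycolytic genes rose in 5 of 16 cases, also when adjusted over the list alone, including Gpi1 by 0.63 (SE 0.08), Pfkfb3 by 0.87 and Hk2 by 0.87 (camera adjusted p = 0.00703, and adjusted p = 0.132 with an estimated correlation). Pfkfb3 lost its limma call without control replicate 2 (adjusted p = 0.0567) or STAM replicate 2 (0.0504), as did Hk2 (0.0692 in each case), which was also lost without STAM replicates 1 (0.0759) and 4 (0.0615).

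Among the largest changes in genes above the median expression with no overlap between groups, Cdkn1a (NM_001111099, chromosome 17, 29090986 to 29100722), the cell-cycle inhibitor p21, went from 3.68 ± 0.92 to 6.30 ± 0.22 log2 CPM (mean ± SD, n = 5 per group), a 6.16-fold rise (limma adjusted p = 0.00438). Socs2 (NM_007706, chromosome 10, 95411490 to 95416857), which is induced by growth hormone, went from 6.58 ± 0.50 to 3.99 ± 0.56 log2 CPM (mean ± SD, n = 5 per group), a 6.02-fold fall (limma adjusted p = 0.00104). Sex-biased cytochromes went both ways. Cyp3a41a (NM_017396, chromosome 5, 145694049 to 145720136) rose by 4.45 (SE 0.84), Cyp4a12b (NM_172306, chromosome 4, 115411624 to 115439034) by 3.48 (SE 0.52), Cyp4a12a (NM_177406, chromosome 4, 115299046 to 115332815) by 2.82 and Mup20 (NM_001012323, chromosome 4, 62050235 to 62054117) by 2.63, with limma adjusted p from 0.00388 to 0.0143. Cyp2b13 (NM_007813, chromosome 7, 26061495 to 26096196) fell by 2.73 (SE 0.44) and the organic anion carrier Slc22a26 (NM_146232, chromosome 19, 7781981 to 7802667) by 1.96. The hepatocyte factor Onecut1 (NM_008262, chromosome 9, 74861921 to 74889647) fell by 1.95 and the receptor Adgrf1 (NM_133776, chromosome 17, 43270347 to 43324406) by 1.74, with limma adjusted p of the 4 from 0.00614 to 0.0199. Onecut1 lost its call without STAM replicate 1 (limma adjusted p = 0.0509). Of 15 male-biased genes 5 rose, 6 when adjusted over the list alone, namely Cml5 by 4.26, Cyp4a12a, Cyp4a12b, Mup20 and C6 (camera adjusted p = 0.00703, and adjusted p = 0.664 with an estimated correlation). Female-biased genes had 3 higher and 3 lower of 18 (camera adjusted p = 0.296).

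Sinusoidal endothelial markers fell in 3 of 14 cases, Stab2 by 0.48, Kdr by 0.44 and Oit3 by 0.43 (camera adjusted p = 0.000223, and adjusted p = 0.405 with an estimated correlation). Of 18 core hepatocyte genes 4 fell, 6 when adjusted over the list alone with 1 higher. These were Cyp2c29 by 0.78, Alb by 0.34, Fah by 0.27 and Apoa2 by 0.26. The list's camera call (adjusted p = 0.0258, and adjusted p = 0.311 with an estimated correlation) was lost without 4-week control replicate 1 (0.0637) or STAM replicate 4 (0.0636), and 1 rose and 1 fell with total-read scaling. The Alb call (limma adjusted p = 0.0284) was lost with total-read scaling (0.0647) and without control replicates 2, 3 and 5 (0.0763, 0.0514 and 0.0738) or STAM replicates 3, 4 and 5 (0.0621, 0.0558 and 0.0667). Fah was lost without control replicate 2 (limma adjusted p = 0.0562) and STAM replicates 1 (0.0548) and 4 (0.0553), and with total-read scaling (0.0723).

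The 21 other lists were not called at 4 weeks. Of 32 collagen and matrix genes 2 rose, Timp1 by 2.82 and Mmp13 by 2.62, and 1 when adjusted over the list alone (camera adjusted p = 0.591, and adjusted p = 0.971 with an estimated correlation). At the preset correlation camera called this list without control replicate 3 (adjusted p = 0.0213). Timp1 (limma adjusted p = 0.0383) lost its call without STAM replicate 5 (0.095) and 5 other single libraries, and under quantile normalization (0.0626). Log2 fold changes were 0.46 for Col1a1 and 0.79 for Acta2 (limma adjusted p = 0.746 and 0.661). In the acute phase list 7 rose and 4 fell of 20 (camera adjusted p = 0.0864). Integrated stress genes had 5 higher and 1 lower of 22 (camera adjusted p = 0.139, and adjusted p = 0.664 with an estimated correlation). At the preset correlation camera called them without STAM replicate 2 (adjusted p = 0.0396). The unfolded protein response had only Xbp1 lower, by 0.44 (camera adjusted p = 0.533). Leaving out 4-week control replicate 1 brought camera calls for proliferation (adjusted p = 1.12e-09 against 0.924), cholesterol synthesis (8.89e-16 against 0.0951), fatty acid and triglyceride synthesis (9.98e-05 against 0.186), stellate cells (0.0153 against 0.139) and the acute phase (0.0148). These calls are shown at the preset correlation only. Camera with an estimated correlation was run on all libraries alone (adjusted p = 0.989, 0.955, 0.955, 0.734 and 0.508). The estimated correlations of the first 2 lists were 0.886 and 0.931, far above the preset 0.01. Without it Mki67 fell by 0.98 (limma adjusted p = 0.041), against a log2 fold change of 0.01 with it (0.997). Srebf1 fell by 0.87 (limma adjusted p = 0.013), while log2 fold changes were -0.19 for Scd1, -0.03 for Fasn, 0.39 for Cpt1a and -0.15 for Cyp4a14 (limma adjusted p = 0.906, 0.984, 0.0694 and 0.777). They were 0.91 for Cyp7a1, 1.03 for Cyp8b1 and 0.26 for Pck1 (limma adjusted p = 0.55, 0.0972 and 0.37). Fgf21 had a log2 fold change of 1.87 (limma adjusted p = 0.126) and was called without STAM replicate 2 (0.0254), and Cpt1a was called with total-read scaling (0.0251). Of the 13 camera calls, 11 were higher and 2 lower. Fry called 12 lists, 11 of them also called by camera. It did not call sinusoidal endothelial markers (fry adjusted p = 0.0572) or male-biased genes (0.0861). With an estimated correlation the lowest adjusted p of camera was 0.132.

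The third comparison asked the same at 10 weeks of age, in mice on the high-fat diet. In these livers, matrix, macrophage, cell-division, lipid-droplet, interferon and fetal genes rose, while genes of protein folding and core hepatocyte functions fell, as did 10 of 24 genes of cholesterol synthesis. Limma called 7319 of 15312 genes, 3876 higher and 3443 lower, of which 2175 changed by at least 1 on the log2 scale. Total-read scaling moved the median by 0.29 and gave 88.0% higher among 7972 called genes, against 53.0% as reported and 44.9% with quantile normalization.

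Collagen and matrix genes rose in 31 of 32 cases, 31 also when adjusted over the list alone, with Mmp14 not called (camera adjusted p = 1.79e-11, and adjusted p = 0.361 with an estimated correlation). Col1a1 rose by 2.89 (95% interval 1.5 to 4.28, limma adjusted p = 0.00426), Timp1 by 3.65 (SE 0.82), Mmp13 by 4.40 (SE 0.48) and Thbs1, an activator of TGF-beta, by 3.16 (SE 0.33). Acta2 had a log2 fold change of 0.43 (limma adjusted p = 0.617), and of 17 stellate cell markers 8 rose and 2 fell (camera adjusted p = 0.229). Macrophage markers rose in 18 of 19 cases, 18 also when adjusted over the list alone. Mmp12 rose by 6.48 (SE 0.46), Gpnmb by 5.92 (SE 0.62), Cx3cr1 by 3.19 and Trem2 by 2.96 (limma adjusted p = 4.48e-05 for Trem2). Camera called this list (adjusted p = 6.18e-08, and adjusted p = 0.315 with an estimated correlation). Cytokines rose in 11 of 20 cases, 11 also when adjusted over the list alone, such as Ccl3 by 3.63, the interleukin antagonist Il1rn by 2.63 and Cxcl2 by 2.46. T and NK cell markers rose in 9 of 19 cases, also when adjusted over the list alone, including Cd8b1 by 2.64 and Ccl5 by 2.20. Pdcd1, the PD-1 receptor, had 24 reads in STAM and none in controls, at least 6.999-fold higher (limma adjusted p = 5.67e-05). Neutrophil granule markers rose in 6 of 13 cases, 10 when adjusted over the list alone. Ngp had 3 reads against 64, a ratio of 18.7 (counting interval 6.11 to 92.9), and Ltf 1 against 47, a ratio of 41.1 (7.03 to 1658). Camp had none against 13, at least 3.79-fold higher. Camera called the cytokine, T cell and neutrophil lists (adjusted p = 0.00521, 0.0063 and 0.00709, and adjusted p = 0.362, 0.362 and 0.396 with an estimated correlation). All 3 were lost with total-read scaling (0.0803, 0.16 and 0.149). Camp lost its limma call without STAM replicate 5 (adjusted p = 0.0517) and under quantile normalization (0.232), as did Cd8b1 (0.103) and Cxcl2 (0.129). Ccl2 and Tnf had log2 fold changes of 0.99 and 0.86 (limma adjusted p = 0.0686 and 0.0807). Ccl2 was called without control replicate 1 (0.00626) and Tnf without STAM replicate 4 (0.0385), and both were called with total-read scaling (0.0222 and 0.0261).

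Proliferation genes rose in 24 of 27 cases, also when adjusted over the list alone. Cenpf rose by 4.60, Ccnb1 by 4.39, Cdc20 by 3.96 and Mki67 by 2.33 (SE 0.24, limma adjusted p = 1.21e-05), and Tk1 fell by 1.45 (camera adjusted p = 1.61e-07, and adjusted p = 0.357 with an estimated correlation). Fetal and tumour genes rose in 10 of 15 cases, 12 when adjusted over the list alone. Ly6d rose by 7.09 (136-fold, limma adjusted p = 1.03e-06) and Afp by 3.76 (SE 0.39, limma adjusted p = 8.2e-06), and Igf2bp3, an RNA-binding protein of fetal liver, had 3 reads in controls and 939 in STAM, a ratio of 274 (counting interval 93.4 to 1330). Camera called the list (adjusted p = 3.47e-05, and adjusted p = 0.315 with an estimated correlation). Ductular markers rose in 10 of 14 cases, also when adjusted over the list alone, with Krt23 up by 3.56, Cftr by 3.10 and Cldn4 by 2.77 (camera adjusted p = 0.00189, and adjusted p = 0.415 with an estimated correlation). Interferon response genes rose in 19 of 23 cases, also when adjusted over the list alone. Usp18 rose by 2.16 (SE 0.13, limma adjusted p = 1.67e-07), Oas1a by 1.5 and Ifi44 by 1.31, while Stat2 fell by 0.34 (camera adjusted p = 5.73e-06, and adjusted p = 0.315 with an estimated correlation).

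Lipid droplet genes rose in 13 of 16 cases, also when adjusted over the list alone (camera adjusted p = 2.29e-07, and adjusted p = 0.29 with an estimated correlation). Apoa4 (NM_007468, chromosome 9, 46240844 to 46243458), an apolipoprotein of triglyceride-rich particles, went from 6.67 ± 0.44 to 11.51 ± 0.43 log2 CPM (mean ± SD, n = 5 per group), a 28.6-fold rise (limma adjusted p = 4.23e-07). Cidec (NM_001301295, chromosome 6, 113424634 to 113435760) rose 22.8-fold, Mogat1, which makes diacylglycerol, by 4.55, and the droplet protein Cidea had 2 reads in controls and 1203 in STAM, a ratio of 526 (counting interval 145 to 4350). Other large rises were Rgs16 (NM_011267, chromosome 1, 153740353 to 153745468), a regulator of G-protein signalling, by 4.81 and the leptin receptor Lepr (NM_146146, chromosome 4, 101717407 to 101815354) by 4.59, from 1.40 ± 0.59 to 5.99 ± 0.42 log2 CPM. Osbpl3 (NM_001163645, chromosome 6, 50293327 to 50456170), a lipid-binding protein, rose by 3.95. Fatty acid oxidation genes rose in 15 of 31 cases, 16 when adjusted over the list alone and 26 with total-read scaling. Cyp4a31 rose by 2.38, Pdk4 by 2.11, Acot2 by 2.02 and Cpt1a by 1.02 (SE 0.09, limma adjusted p = 2.65e-06). Camera called the list (adjusted p = 0.000278, and adjusted p = 0.512 with an estimated correlation). Gluconeogenic and insulin-suppressed genes rose in 10 of 14 cases, also when adjusted over the list alone. Igfbp1 rose 10.8-fold (limma adjusted p = 1.47e-05), Got1 by 1.90, Irs2 by 1.18 and Pck1 by 0.45 (camera adjusted p = 0.000293, and adjusted p = 0.315 with an estimated correlation). Integrated stress genes rose in 16 of 22 cases, also when adjusted over the list alone. Stc2 rose by 3.71, Fgf21 by 3.66 (SE 0.70, limma adjusted p = 0.00187) and Chac1 by 1.83 (camera adjusted p = 0.000432, and adjusted p = 0.315 with an estimated correlation).

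All 16 genes of the unfolded protein response fell, 16 also when adjusted over the list alone and 15 with total-read scaling. Sdf2l1 fell by 2.13, Creld2 by 1.78 and Hyou1 by 1.71 (camera adjusted p = 1.48e-10, and adjusted p = 0.315 with an estimated correlation). Core hepatocyte genes fell in 14 of 18 cases, also when adjusted over the list alone, and in 8 with total-read scaling, while quantile normalization gave 6 lower and 1 higher (camera adjusted p = 3.63e-05, and adjusted p = 0.315 with an estimated correlation). Cyp2c29 (NM_007815, chromosome 19, 39287085 to 39330713) went from 11.02 ± 0.18 to 7.01 ± 0.62 log2 CPM (mean ± SD, n = 5 per group), a 16.2-fold fall (limma adjusted p = 1.64e-06). Cyp3a11 fell by 2.19 and Alb fell by 0.96 (SE 0.18, limma adjusted p = 0.000648). Quantile normalization sets Alb to 0 change by construction in each comparison, since it had the highest value of every library. Further large falls were Hsd3b5 (NM_008295, chromosome 3, 98618636 to 98645534), a male-biased steroid enzyme, by 5.87 (SE 0.96) and Cyp2c70 (NM_145499, chromosome 19, 40153361 to 40187286), which makes muricholic acids, by 3.68. Cyp2c40 (NM_010004, chromosome 19, 39767073 to 39812814) fell by 3.29 and Gm6484 (NM_001080940, chromosome 9, 21835510 to 21837347) by 3.24. Cholesterol synthesis genes fell in 10 of 24 cases, also when adjusted over the list alone, and in 8 with total-read scaling. Insig1 fell by 1.63 and Tm7sf2 by 1.48 (camera adjusted p = 3.63e-05, and adjusted p = 0.512 with an estimated correlation). Bile acid genes fell in 12 of 21 cases, also when adjusted over the list alone. Nr0b2 fell by 2.15, Cyp7b1 by 1.45 and Akr1d1 by 1.37, whereas Cyp8b1 rose by 1.64 (SE 0.21, limma adjusted p = 9.84e-05) and Abcb4 by 0.93. With total-read scaling 8 fell and 7 rose (camera adjusted p = 0.0167, and adjusted p = 0.47 with an estimated correlation). Male-biased genes fell in 7 of 16 cases, also when adjusted over the list alone, among them Slco1a1 by 2.32 and Serpina1e by 1.98, and Mup20 rose by 0.71. Acute phase genes fell in 7 of 20 cases, 6 when adjusted over the list alone, such as Crp by 0.96, Fgb by 0.83 and Fga by 0.77, and Serpina3n rose by 0.83. The camera calls of these lists (adjusted p = 0.0183 and 0.0192, and adjusted p = 0.563 and 0.645 with an estimated correlation) were lost without control replicate 1 (0.0739 and 0.238). With total-read scaling 6 male-biased genes fell and 3 rose.

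The 15 other lists were not called by camera at 10 weeks. Fatty acid and triglyceride synthesis had 7 higher and 5 lower of 20 (adjusted p = 0.562), with log2 fold changes of 0.49 for Scd1, 0.20 for Fasn and -0.34 for Srebf1 (limma adjusted p = 0.271, 0.629 and 0.124; Srebf1 was called without STAM replicate 3 at 0.0377). Methionine and choline genes had 4 higher and 13 lower of 30, with a median of -0.19 and a mean of 0.04 (camera adjusted p = 0.0902). Kupffer cell markers had 2 higher and 2 lower of 11 (0.641), with Clec4f at 0.10 and Timd4 at -0.73 (limma adjusted p = 0.602 and 0.124), and Clec4f was called with total-read scaling (0.0287). Sinusoidal endothelial markers had 7 higher and 1 lower of 14 (camera adjusted p = 0.136), and NRF2 targets 7 higher and 6 lower of 24 (0.516), with Nqo1 up by 1.04 (limma adjusted p = 0.000567). Cyp7a1 and Cyp4a14 had log2 fold changes of 0.79 and 0.87 (limma adjusted p = 0.13 and 0.182), and Cyp7a1 was called with total-read scaling (0.0454). Of the 19 camera calls, 13 were higher and 6 lower. Fry called 26 lists, 18 of them also called by camera, but not the acute phase list (fry adjusted p = 0.102). With an estimated correlation the lowest adjusted p of camera was 0.29.

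**Figure D2:**
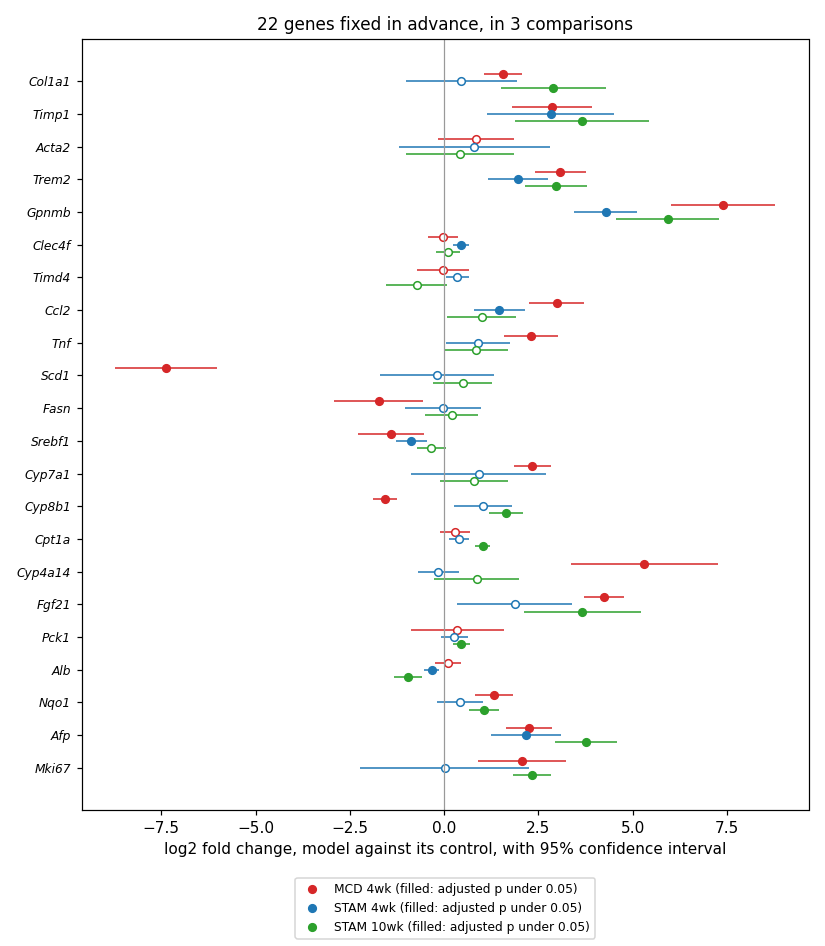
Log2 fold change of 22 of the 24 genes fixed before the data were examined, in MCD against CD, STAM against control at 4 weeks and STAM against control at 10 weeks, with 95% confidence intervals of limma; filled symbols have an adjusted p under 0.05. Scd1 lies at -7.38 in MCD and at -0.19 and 0.49 in STAM, while Gpnmb lies at 7.40, 4.28 and 5.92 (n = 4 or 5 per group).

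Whether the STAM effect differed between the ages was tested as the 10-week effect minus the 4-week effect. By the design text the high-fat diet began at 4 weeks, so the ages also differ in time on that diet. The test does not separate age from time on the diet. The STAM effect on collagen genes was higher at 10 weeks, and that on protein folding and male-biased genes lower. Limma called 3011 of 15022 genes, 1335 with a higher and 1676 with a lower effect at 10 weeks. Of these, 2450 were called at 10 weeks alone, 152 at 4 weeks alone, 243 at both ages (56 in opposite directions) and 166 at neither. Metallothioneins Mt2 (NM_008630, chromosome 8, 94172618 to 94173567) and Mt1 (NM_013602, chromosome 8, 94179089 to 94180327), which bind zinc and copper, had effects higher at 10 weeks by 3.73 (SE 1.14) and 3.64 (SE 0.85). Socs2 differed by 3.49 (SE 0.40, limma adjusted p = 3.11e-05), Cyp2a4 by 3.46 and Rgs16 by 3.39. Lower effects at 10 weeks were found for the acute phase protein Saa1 (NM_009117, chromosome 7, 46740499 to 46742980), at -3.61 (SE 1.24), Cyp2c70 at -3.43, Cyp2c69 (NM_001104525, chromosome 19, 39842660 to 39886769) at -3.38, Cyp2b10 (NM_009999, chromosome 7, 25897658 to 25926624) at -3.33 and Cyp2c29 at -3.24 (SE 0.30, limma adjusted p = 2.95e-06). Saa1 (limma adjusted p = 0.0497) lost its call with total-read scaling (0.0558), under voom (0.0661) and without most single libraries, for example 10-week control replicate 3 (0.0769). Mt2 (limma adjusted p = 0.0297) lost it without 10-week control replicate 2 (0.0535) or 4 (0.0534), STAM replicate 2 at 10 weeks (0.0501), 4-week control replicate 2 (0.0552) or STAM replicate 3 at 4 weeks (0.0555). With total-read scaling, 84.3% of 3437 called genes had a higher effect at 10 weeks, against 44.3% as reported.

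Of 32 collagen and matrix genes 23 had a higher effect at 10 weeks, 30 when adjusted over the list alone (camera adjusted p = 9.86e-13, and adjusted p = 0.382 with an estimated correlation). The unfolded protein response was lower in 15 of 16 cases, also when adjusted over the list alone (camera adjusted p = 1.71e-12, and adjusted p = 0.138 with an estimated correlation), and male-biased genes in 11 of 15, 12 when adjusted over the list alone (1.06e-07, and adjusted p = 0.311 with an estimated correlation). Fatty acid oxidation was higher in 11 of 31 cases, 12 when adjusted over the list alone, and sinusoidal endothelial markers in 8 of 14 (camera adjusted p = 0.000119 and 0.000213, and adjusted p = 0.476 and 0.455 with an estimated correlation). Core hepatocyte genes were lower in 9 of 18 cases and gluconeogenic genes higher in 5 of 14 (camera adjusted p = 9.29e-05 and 0.000213, and adjusted p = 0.138 with an estimated correlation for each). Proliferation, with 4 of 27 genes higher and a median of 1.85, was called by camera (adjusted p = 0.000346, and adjusted p = 0.48 with an estimated correlation). Interferon genes had 7 lower and 1 higher of 23 (camera adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation), a call lost without 4-week control replicate 1 (0.102) or 10-week control replicate 1 (0.0584). Camera called 21 lists, 12 higher and 9 lower, and with an estimated correlation its lowest adjusted p was 0.138.

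Whether the models differed was tested as the MCD effect minus the 10-week STAM effect. The labels also give different times for the MCD and STAM livers. The test thus does not separate the kind of model from age and length of exposure. The effects of MCD on interferon, gluconeogenic, and fatty acid and triglyceride synthesis genes were lower than those of STAM, and effects on female-biased genes higher. Limma called 4178 of 14986 genes, 1929 with a higher and 2249 with a lower effect in MCD. Of these, 1583 were called in MCD alone, 1212 in STAM alone, 1197 in both (509 in opposite directions) and 186 in neither. Higher effects in MCD were found for Cyp2b9 (6.73, SE 1.58), Gm6484 (5.40, SE 0.61), Slc16a5 (5.29, SE 0.31, limma adjusted p = 3.53e-09), Cyp2c38 (NM_010002, chromosome 19, 39389556 to 39463075; 5.28) and the hepcidin gene Hamp2 (NM_183257, chromosome 7, 30922372 to 30924181; 5.04). Lower effects were found for Mup7 (-10.49, SE 0.94), Mup14 (-9.12), Scd1 (-7.87, SE 0.68, limma adjusted p = 1.23e-06), Mup12 (NM_001199995, chromosome 4, 60737381 to 60741281; -6.74) and Mup9 (NM_001281979, chromosome 4, 60418046 to 60421952; -6.40). Cyp2b9 lost its call under voom (limma adjusted p = 0.0639). With total-read scaling, 62.5% of 4272 called genes had a higher effect in MCD, against 46.2% as reported.

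Interferon genes had a lower effect in MCD in 21 of 23 cases (camera adjusted p = 4.85e-14, and adjusted p = 0.0799 with an estimated correlation). Female-biased genes were higher in 13 of 18 cases, 14 when adjusted over the list alone (camera adjusted p = 3.04e-10), the only call that held with an estimated correlation (adjusted p = 0.00146). Male-biased genes were lower in 11 of 16 cases, 12 when adjusted over the list alone, fatty acid and triglyceride synthesis in 14 of 20, 15 when adjusted over the list alone, and gluconeogenic genes in 10 of 13. Camera called these 3 (adjusted p = 1.02e-08, 1.83e-07 and 1.68e-06, and adjusted p = 0.199, 0.311 and 0.0799 with an estimated correlation). Cholesterol synthesis genes had a higher effect in MCD in 9 and a lower one in 2 of 24 cases, 9 and 2 also when adjusted over the list alone (camera adjusted p = 0.00706, and adjusted p = 0.817 with an estimated correlation). Collagen genes had a lower effect in MCD in 6 of 32 cases (camera adjusted p = 0.0191, and adjusted p = 0.817 with an estimated correlation), a call lost without CD replicate 1 (0.0527) or 10-week STAM replicate 5 (0.095). Integrated stress genes were higher in 9 and lower in 1 of 22, 11 and 1 when adjusted over the list alone (camera adjusted p = 6.16e-05, and adjusted p = 0.16 with an estimated correlation). Fatty acid oxidation had 4 higher and 12 lower of 31, with a median of -0.31 and a mean of 0.10 (camera adjusted p = 0.0381, and adjusted p = 0.817 with an estimated correlation), a call lost without CD replicate 2 (0.206), MCD replicate 1 (0.0973), 10-week control replicate 1 (0.166) or 3 (0.0521), or 10-week STAM replicate 1 (0.0548) or 5 (0.0929). Camera called 13 lists, 4 higher and 9 lower.

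Log2 fold changes were correlated across genes between the comparisons, which share no control library. Spearman's rho was 0.516 between MCD and 10-week STAM over 14986 genes (jackknife SE 0.0433), 0.338 between MCD and 4-week STAM over 14962 genes (SE 0.0890) and 0.410 between the ages of STAM over 15022 genes (SE 0.111). Genes are not independent replicates, so no p is given for these 3 values. MCD and 10-week STAM shared 1847 genes that rose and 1506 that fell, where independent lists would share 869 and 705, and 263 and 246 genes went opposite ways, where 782 and 784 would. Of the genes that rose at 4 weeks of STAM, 70.5% also rose at 10 weeks, and of those that fell, 61.3% also fell. In all 3 comparisons 460 genes rose and 210 fell of 14848 tested, against 57.7 and 23.9 for independent lists. For MCD, 4-week and 10-week STAM, the authors' deposited table had 6187, 1433 and 6601 genes with an adjusted p under 0.05, of which 5966, 1220 and 6394 were also called here in the same direction.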

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

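Of the tests below, the placing of 4-week control replicate 1 between the ages, its swap and depth tests, the comparison of macrophage with endothelial scores, total-read scaling for the hepatocyte genes and all 4 tests on sex-biased genes were chosen only after the result was seen, as were camera on the age and model differences.

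The gap between 1 library and the rest of its group exceeded Dixon's 95% critical value in 53 of 670 groups of values, where chance gives about 1 in 20; 8 of them were in 4-week control replicate 1 and 7 in 10-week STAM replicate 5. Values are log2 CPM, or log2 differences from the control mean for list scores. In 4-week control replicate 1 these were the scores of proliferation (-3.20), cholesterol synthesis (-1.67) and fatty acid and triglyceride synthesis (-1.01), and Cyp3a41a (-0.35), Gpi1 (7.23), Scd1 (10.96), Fasn (8.20) and Mki67 (1.64). Among other 4-week controls they were the pancreas score (0.64) and Fah (8.86) in replicate 2, the adipocyte (3.23), lipid droplet (0.74) and integrated stress (0.18) scores and Cyp7a1 (3.81) in replicate 3, Timp1 (-6.25) in replicate 4 and Apoa4 (6.60) in replicate 5. In 4-week STAM livers the B cell score (-0.46) and Clec4f (7.37) in replicate 5, the neutrophil score (1.79) in replicate 4, the fetal score (1.34) in replicate 3 and Ly6d (4.96) in replicate 2 stood apart.

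In CD livers they were Cxcl2 (-4.01) and Srebf1 (8.23) in replicate 1, Mmp12 (-1.89) and Afp (2.27) in replicate 2, Cidec (0.42) in replicate 3 and Cyp3a41a (-6.47) in replicate 4. In MCD livers they were the fatty acid oxidation score (0.52) and Mx2 (3.50) in replicate 1, Moxd1 (-4.28) in replicate 2, and Timd4 (4.35) and Alb (15.71) in replicate 4. Among 10-week controls, replicate 1 had Alb at 4.70% of reads and 15.71 log2 CPM, Gpnmb at -0.72 and Stc2 at -6.39, replicate 2 the glycolysis score at -0.14 and Ltf at -4.05, replicate 3 Cftr at -2.68 and Oas1a at 2.63, and replicate 5 Thbs1 at -1.44. In 10-week STAM livers, replicate 5 had the ductular score at 2.76, Cldn4 at 0.98, Cyp3a11 at 10.79, Pdk4 at 6.25, Acot2 at 6.66, Ifi44 at 3.19 and Timd4 at 1.21. Replicate 3 had the female-biased score at 0.29, Cenpf at 0.56 and Cdc20 at 0.40, and replicate 4 had Pdcd1 at -3.17 and Krt23 at 3.72.

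The effects of STAM at the 2 ages differed in 3011 genes by limma's interaction and 21 lists by camera, of which 0 were called with an estimated correlation (lowest camera adjusted p = 0.138). The 10 genes named for this were Mt2 (3.73), Mt1 (3.64), Socs2 (3.49), Cyp2a4 (3.46), Rgs16 (3.39), Saa1 (-3.61), Cyp2c70 (-3.43), Cyp2c69 (-3.38), Cyp2b10 (-3.33) and Cyp2c29 (-3.24), as log2 differences of the effects. Between MCD and 10-week STAM 4178 genes and 13 lists differed, of which 1 list was called with an estimated correlation (camera adjusted p = 0.00146). Named here were Cyp2b9 (6.73), Gm6484 (5.40), Slc16a5 (5.29), Cyp2c38 (5.28), Hamp2 (5.04), Mup7 (-10.49), Mup14 (-9.12), Scd1 (-7.87), Mup12 (-6.74) and Mup9 (-6.40).

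Only 1 of 35 splits, the real one, gave 6541 genes for MCD, the smallest share that so few libraries can give. For STAM at 4 and 10 weeks, 1 of 100 splits gave 1500 and 7319 genes. The highest other split called 0 genes by limma in each case, which argues against a chance division of the samples for these counts. For the age difference 1 of 100 splits gave 3011 genes, and the highest other called 0. For the model difference 1 of 100 splits gave 4178 genes, and the highest others, 3594 and 2028, kept the real MCD groups. Splits for the age and model differences moved labels within each table. They test for no effect in either table, not for equal effects, so they cannot exclude chance for these 2 differences. For the number of lists, 2 of 100 splits, the real one included, gave as many as 21 for the age difference. The highest other split also gave 21 and the median of the others was 11. With 0 of these lists called at an estimated correlation, chance is not excluded for this count. As many lists as the real 18, 13, 19 and 13 were found in 11 of 35 splits for MCD (highest other 22), 17 of 100 for 4-week STAM (17), 19 of 100 for 10-week STAM (24) and 39 of 100 for the model difference (24), so the counts of lists at a preset correlation are not beyond chance there. Correlations as large as 0.516, 0.338 and 0.410 came from 2, 4 and 2 of 100 splits, with highest others of 0.537, 0.374 and 0.437.

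Control replicate 1 at 4 weeks differed from the other 4 controls by more than 2-fold in 475 of 10208 genes, against at most 130 in the other 9 libraries of its table. A STAM liver under a control's name is argued against by its place at 0.0716 on the axis from controls (0) to STAM (1), and a swap with a 10-week control by the slopes of those controls' deviations within their own table on the deviation of this library over the 475 genes, of which the lowest was -0.152 (SD 0.111, n = 5), where a swapped partner would lie near -1. Its depth, 16.2 M reads against 17.6 to 22.1 M, is argued against by 390 of the 475 genes having at least 100 reads at their mean level. On an axis from 4-week (0) to 10-week controls (1) it lay at 0.387, so an older or otherwise different control may be a candidate explanation, which cannot be told apart here because that axis mixes age with separately scaled tables. No biological explanation was tested.

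Core hepatocyte genes fell while macrophage, ductular and collagen genes rose in MCD and in STAM at 10 weeks. A lower share of hepatocytes with other cells kept would raise markers of all other cells alike, but macrophage exceeded endothelial scores by 2.19 ± 0.30 (SD, n = 4) in MCD and 1.68 ± 0.44 (SD, n = 5) in 10-week STAM. The authors' scaling factors as the whole source are argued against by 10 and 8 hepatocyte genes being lower with total-read scaling, against 12 and 14 as deposited. Under quantile normalization 3 and 6 were lower and 4 and 1 higher, with list medians of 0.04 and -0.18, so the fall depends on the normalization, which stays open, and in MCD the median was no longer below 0. A larger share of macrophages and duct cells, and lower expression within hepatocytes, both stay open and were not tested.

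In MCD livers male-biased genes fell and female-biased genes rose. Female animals are argued against by the Y-linked genes, whose summed CPM was at lowest 86.0% of the CD mean, and reads shared within families by the 9 of 9 members outside large families that moved in the list's direction. Of 4 genes that growth hormone induces through STAT5, 3 were lower in MCD (Igf1 by 1.40, Igfals by 1.46 and Cish by 2.33; Socs2 was at -0.66, limma adjusted p = 0.551), consistent with lower growth hormone signalling as a candidate explanation. A partly different 3 of the 4 were lower in 4-week STAM (Igfals by 0.74, Socs2 by 2.59 and Cish by 1.73), where 5 male-biased genes rose. Igf1 was at -0.08 there (limma adjusted p = 0.761). Whether male-biased genes stood high enough in livers of that age to fall was not tested. The 4-week values therefore do not decide whether lower growth hormone signalling would be sufficient. In 10-week STAM, where 7 male-biased genes fell, Igf1 fell by 0.42 and Igfals fell by 1.53, but Socs2 rose by 0.90 (limma adjusted p = 0.00372) and Cish was at 0.50 (0.607).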

How the results depend on the processing

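Voom on recovered reads, total-read scaling, a prior of 2 reads, the tests without the replicate 1 controls of both ages and camera on the differences were chosen only after the data were seen. Counts of genes stayed within 1.5 times of those reported under limma without trend or robust estimation, quantile normalization, both filters, voom, total-read scaling and a prior of 2 reads, although total-read scaling turned most calls upward. With a log2 fold change of at least 1 they were 2637, 480, 2175, 875 and 1472 for MCD, STAM at 4 and 10 weeks, age and model, fewer by construction. The replicate number did not pair the samples, since 0 of 4, 5 and 5 same-numbered pairs correlated above 0.1 (ranges -0.122 to 0.00824, -0.118 to -0.000852 and -0.0598 to -0.0223) and 0 correlated best with their own number. With it as a block, 4-week STAM had 848 genes, 829 of them shared with the 1500, and MCD 5507, 10-week STAM 6566, age 2071 and model 3234.

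Leaving out single libraries gave 5732 to 6217 genes for MCD, 982 (without STAM replicate 1) to 1821 (without control replicate 1) for 4-week STAM, 6596 to 7421 for 10-week STAM, 2435 to 3802 for age and 3679 to 4312 for model. Lists numbered 17 to 20, 11 to 17, 17 to 20, 18 to 22 and 9 to 14. Correlations were 0.490 to 0.527 for MCD with 10-week STAM, 0.256 to 0.360 for MCD with 4-week STAM and 0.306 to 0.456 between the ages, the lower ends of the last 2 without 4-week control replicate 1. Camera with an estimated correlation called 0, 0, 0, 0 and 1 lists, where fry called 22, 12, 26, 16 and 13, and the strict filter left 13 lists for age and 8 for model, the cause of which was not tested. Over called genes alone the correlations were 0.581, 0.432 and 0.551, and that of MCD with 10-week STAM was 0.426 with the strict filter and 0.392 under quantile normalization; the cause was not tested.

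Results that reversed were Apoa1 in MCD under quantile normalization (0.043, limma adjusted p = 0.822), Mki67 in 4-week STAM, which was -0.98 without control replicate 1 and at most 0.35 without control replicate 4, and cholesterol synthesis for age (camera adjusted p = 0.865) without the replicate 1 controls of both ages; the cause was not tested. Alb was at 0 under quantile normalization by construction, which ended its calls in STAM. Of the list results with single libraries left out, 2174 stayed on their side of the threshold, 23 gained a call and 47 lost one. The count models, size factors and linear pseudocounts listed before the data were examined did not apply to log2 values and were not run. Depth limits genes with few reads, for which ratios above carry wide counting intervals.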

Other observations

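No test was chosen here after a result was seen other than the naming of genes; those named below outside the fixed lists were picked after their values were seen. Of 24 targets of the oxidant sensor NRF2, 8 were higher and 4 lower in MCD, 3 higher and 0 lower in 4-week STAM by limma, and 7 higher and 6 lower in 10-week STAM. The cystine importer Slc7a11 rose by 8.65 in MCD, 4.69 in 4-week STAM and 6.91 in 10-week STAM on the log2 scale, and the carbonyl reductase Cbr3 by 4.25, 4.19 and 3.25. In methionine and choline metabolism on the MCD diet, the serine synthesis enzyme Psat1 rose by 5.67 and the mitochondrial folate enzyme Mthfd2 by 2.75, while Gnmt, which disposes of methyl groups, fell by 1.28 and Ahcy fell by 1.18. Among the 460 genes higher in all 3 comparisons were Ly6d (5.17, 5.23 and 7.09 in the same order), Rasl10b (2.90, 2.87 and 2.92), the citrate importer Slc13a5 (1.74, 3.0 and 2.38) and Shc2 (1.36, 4.18 and 5.73). Among the 210 lower in all 3 were the endothelial growth factor Vegfa, which fell by 0.57, 0.77 and 0.83, the phospholipid flippase Atp8b1, which fell by 0.99, 0.76 and 0.83, and the chemokine Cxcl12, which fell by 1.01, 0.39 and 1.0.

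Some lists were called in none of the 3 comparisons by camera. Circadian clock genes had 7 lower and 1 higher of 18 in MCD (adjusted p = 0.121) and 6 lower and 3 higher in 10-week STAM (0.224). Pericentral hepatocyte genes had 3 higher and 3 lower of 15 in MCD (0.598) and 3 higher and 6 lower in 10-week STAM (0.256). Of 10 B cell markers 1 rose in MCD (0.72) and 1 in 10-week STAM (0.536). Erythroid markers had 1 lower of 6 in MCD (0.0945) and 4 higher and 1 lower of 9 in 10-week STAM (0.145). Markers of tissues next to the liver were few among tested genes, with 2 higher and 1 lower of 6 exocrine pancreas genes in MCD (0.887) and 1 of 4 higher in 10-week STAM (0.438), and 1 of 8 adipocyte genes lower in MCD (0.34) and 1 of 5 higher in 10-week STAM (0.52).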
